A study of Mus musculus with 12 samples.

How the data were processed

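Messenger RNA and ribosome footprints were measured in 12 libraries from 6 mice, 3 fasted and 3 refed. Per the labels, mRNA was selected on poly(A) beads and prepared with a directional kit. Footprints were made from flash-frozen tissue ground in liquid nitrogen after a rinse with cycloheximide, which halts ribosomes, and were selected by size, reverse transcribed, circularized and amplified. No molecular identifiers are described, so that intervals and limits cover counting error only. The submitters' processing notes name bcl2fastq 1.8.4 and the mouse build GRCm38. The aligner, the quantification program and the annotation release are not given in the sources used here.

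The deposited files hold 1 record of 5 lines per transcript for each animal. The first value is an estimated count of footprint reads, which the authors deposited without normalization and which is fractional for many transcripts. The second is the transcript's share of the mRNA pool, a deposited fraction that sums to 1 per animal and was multiplied by 1000000 to give values on the TPM scale. The third is the deposited ratio of the first to the second. It was recomputed from them and differed by a relative value of at most 1.34e-05. Which value belongs to which library type was read from the values themselves, and files were assigned to animals by matching their names with the sample titles. In each file, 27.4% to 28.7% of the transcripts with footprints had exactly the ratio of another transcript, as results when shared footprints are divided in proportion to mRNA abundance. If shared footprints were divided in this way, footprint values are not independent of the mRNA library of the same animal. Whole-number values made up 29.1% to 35.0% of the footprint values per animal (exact equality with a whole number). The files name transcripts by Ensembl identifier only, and 0 matched the gene tables used, so that transcripts and not genes were tested.

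The planned tests were count tests, with limma on log2(value + pseudocount) as the fallback where the files hold no counts. mRNA was given as a share of the pool and footprints as estimated counts, many of them fractional. The records were not treated as counts, and the fallback was used at every level. For footprints this is a departure from the condition as planned, since estimated counts were given. R 4.3.3 and limma 3.58.1 were used. Transcripts listed in all 6 animals were kept (21029 of 43347). mRNA had to reach 1 TPM and footprints 10 reads in at least 3 libraries, and translation efficiency both. Values were scaled by trimmed means of M values, written anew without weights (30% of M and 5% of A values trimmed per side), and 1 was added before taking log2. Empirical Bayes moderation used an intensity trend, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Translation efficiency was fitted on the log2 ratio within each animal, which is equivalent to the animal as a block. This pairing comes from the extraction protocol, by which the duodenum of 1 mouse gave both libraries. The deviations of the paired libraries from their group means had correlations of 0.349 to 0.611, all over 0.1, across all transcripts; the report gives the values over transcripts with whole-number footprints. No block was used between fasted and refed mice.

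No library was a copy of another: of the 21029 transcripts listed in all animals, at most 627 had the same footprint value and at most 1 the same mRNA value in any 2 libraries. Pearson correlations of log2 values between libraries were 0.894 to 0.943 within and 0.892 to 0.925 between feeding groups for mRNA, and 0.947 to 0.967 within and 0.938 to 0.957 between groups for footprints. One footprint read corresponded to 0.0749 to 0.418 reads per 1000000, and a value of 0 allows up to 3 reads, or 0.225 to 1.25 reads per 1000000.

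The fit was tested on simulated data with the means, spread and library sizes of the real transcripts, in which 200 transcripts were changed. Errors were drawn independently between transcripts, so that deviations shared by many transcripts of an animal were left out. For mRNA, 0% of 96 transcripts changed by a log2 value of 1 and 28.1% of 96 changed by 2 were recovered, with 1 false call among 28 (19250 transcripts). For footprints, 4.25% of 94 and 62.5% of 80 were recovered, with 5 false calls among 59 (15710 transcripts). For translation efficiency, 0% of 90 and 30% of 80 were recovered, with 0 false calls among 24 (15340 transcripts).

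Transcripts were named by a rule fixed before the data were examined: the largest changes among called transcripts without overlap between the groups and, where fewer than 5 were called, the 5 with the smallest p, said not to pass. Without gene names at most 2 identifiers per direction are printed. The 36 gene lists fixed before the data were examined (19 of functions and 17 of cell types), the ribosomal protein comparison per animal and the removal of a list of transcripts from a neighbouring organ need gene names and were not run. The fixed alternatives that were run were another scaling, no filter, a filter at 5 TPM or 5 reads per 1000000, a pseudocount of 0.1, a block by replicate number, all 12 libraries in 1 fit, and each animal left out. Alternatives added after the data were examined were no scaling, transcripts absent from a file set to 0, transcripts of 1 ratio summed, whole-number transcripts alone, removal of the footprint-rich and footprint-poor sets, transcripts passing the filters of both library types alone, and voom weights. Group shares were compared by exact two-sided permutation tests.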

Results

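To compare the messages present in the mouse duodenum with those being translated there, C57BL/6 mice aged 8 weeks were fasted for 5 h from just before the dark phase, or fasted for 5 h and then given food again for 2 h. The duodenum, the part of the small intestine next to the stomach, was divided into 2 pieces. One piece gave a polyadenylated mRNA library and the other a ribosome profiling library, which holds the short RNA fragments that ribosomes protect from nuclease (footprints). Each of the 4 groups held 3 libraries, and same-numbered mRNA and footprint libraries of a feeding group came from 1 mouse, so that 12 libraries described 6 animals. Refed mice were killed 2 h later than fasted mice, and feeding and time of day therefore moved together in every comparison. The title of the series asks how the placement of mRNAs inside cells of the intestinal epithelium relates to their translation; placement itself was not analysed here.

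The footprint libraries of fasted mice 1, 2 and 3 held 2.39, 6.66 and 4.08 M estimated reads (M, 1000000), against 5.81, 13.3 and 10.2 M in refed mice 1, 2 and 3. The means were 4.38 ± 2.15 M reads (SD, n = 3) for fasted and 9.79 ± 3.79 M reads (SD, n = 3) for refed animals, and fasted mouse 1 had the fewest. The read depth of the mRNA libraries was unknown, because mRNA was given as a share of the pool. Between 29887 and 34289 transcripts were listed per animal, and 21029 were listed in all 6. Within a library, mRNA and footprint values of the transcripts had Spearman correlations of 0.850 to 0.885. The files name transcripts by Ensembl identifier and do not pair them with genes, and 0 of the identifiers matched the reference tables, so that no gene names are given.

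To find messages whose abundance changed on refeeding, mRNA shares were compared between 3 refed and 3 fasted mice. The transcript ENSMUST00000129753 was the only one of 19190 to pass limma's test after Benjamini-Hochberg adjustment. It fell from 42.3 ± 3.66 TPM (SD, n = 3) in fasted mice to 0.386 ± 0.668 TPM (SD, n = 3) in refed mice, a log2 change of -5.12 (SE 0.38, limma adjusted p = 0.028). Its limma adjusted p rose to 0.133 without fasted mouse 2, 0.104 without fasted mouse 3, 0.0672 without refed mouse 1 and 0.0855 without refed mouse 2, and with the pseudocount of 0.1 to 0.166. Among transcripts that did not pass, ENSMUST00000191367 had the smallest p of those with a higher mean in refed mice, with a log2 difference of 3.11 (SE 0.31, limma adjusted p = 0.0712). ENSMUST00000155597 was next among the lower ones, with -2.49 (SE 0.24, limma adjusted p = 0.0712). All fold changes are on the log2(value + 1) scale, which understates the change of low transcripts.

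Differences that did not reach a call were counted as well. At an unadjusted p under 0.05 limma counted 2397 transcripts, 1404 with higher and 993 with lower means in refed mice. Leaving out 1 animal gave 1405 (without refed mouse 1) to 3383 (without fasted mouse 1). The 3 refed and 3 fasted values did not overlap in 3677 transcripts (19.2%, where chance gives 10%). Of these, 670 were more than 2-fold higher and 304 more than 2-fold lower in refed mice. The count of called transcripts depended on single animals. It was 54 (31 higher, 23 lower) without fasted mouse 1, and 0 without fasted mouse 3, without refed mouse 1 or without refed mouse 2. With all 12 libraries in 1 fit, over the 15483 transcripts that passed the filters of both library types, it was 176 (121 higher, 55 lower). This fit had no term for the animal and pooled the spread of both library types. The paired libraries of a mouse thus counted as independent. The 6 mRNA libraries alone, over those 15483 transcripts, gave 1.

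The corresponding comparison of footprints asked which messages were occupied by more or fewer ribosomes after refeeding. Of 15595 transcripts, 1 rose and 4 fell by limma with Benjamini-Hochberg adjustment. ENSMUST00000018094 rose by a log2 value of 2.45 (SE 0.20, limma adjusted p = 0.0261), with 8.78 ± 1.91 (SD, n = 3) footprint reads per 1000000 in fasted and 83.0 ± 27.6 (SD, n = 3) in refed mice before scaling between libraries. ENSMUST00000129753, also called at the mRNA level, had a footprint change of -5.69 (SE 0.43, limma adjusted p = 0.0261). ENSMUST00000115048 had a change of -3.26 (SE 0.19, limma adjusted p = 0.014), from 6.94 ± 1.23 (SD, n = 3) to 0.0749 ± 0.130 (SD, n = 3) reads per 1000000 before scaling between libraries. The other 2 called transcripts carried identical values and shared their reads. All 5 had mRNA changes of the same direction, and the footprint values of all 5 were fractional, as when reads shared by several transcripts are divided among them. If reads were divided in proportion to mRNA, footprint changes take on the mRNA change. The shared direction is then no independent sign of changed ribosome occupancy. At an unadjusted p under 0.05, limma counted 1693 transcripts, 784 higher and 909 lower. Leaving out 1 animal gave 918 (without refed mouse 3) to 2343 (without fasted mouse 1). Higher and lower are relative to the typical transcript, and the share of higher ones was 46.3% here and 45.1% under the other scaling. Without scaling between libraries, an alternative chosen after the data were examined, all transcripts shifted upwards together, and 97.2% of 5331 were higher. The groups did not overlap in 2773 transcripts (17.8%, against 10% by chance), with 158 more than 2-fold higher and 213 more than 2-fold lower.

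All 5 calls were lost with a pseudocount of 0.1, where 2 other transcripts were called, and with voom weights, chosen after the data were examined, where 0 were called. The calls also depended on single animals. Without refed mouse 1 there were 32 calls, without refed mouse 3 there were 2, and without fasted mouse 2, fasted mouse 3 or refed mouse 2 there were 0. Without fasted mouse 1 there were 5, of which 0 were among those of the full comparison. The 5 calls were kept under the other scaling. Without scaling between libraries they were among 15 transcripts called higher and 8 called lower, and the median log2 change of all transcripts was 0.52 instead of 0.01. The share of reads taken by the most abundant transcripts differed as well. The top 10 held 31.3% ± 1.55 (SD, n = 3) of the footprints in fasted mice, and 26.7%, 11.99% and 11.7% in refed mice 1, 2 and 3.

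Translation efficiency, the ratio of footprints to mRNA within each animal, was compared to find messages whose translation changed beyond their abundance. By limma with Benjamini-Hochberg adjustment, 0 of 15483 transcripts passed, while 1941 had an unadjusted p under 0.05 (788 higher, 1153 lower in refed mice). Leaving out 1 animal gave 1084 (without refed mouse 1) to 3215 (without fasted mouse 1). The share of higher ones was 40.6% here and 40.9% under the other scaling. Without scaling between libraries all transcripts shifted upwards together (median log2 difference 0.56 instead of 0.02), and 96.3% of 4697 were higher. The smallest adjusted p was 0.0671. It belonged to ENSMUST00000034214, with a log2 difference of -3.05 (SE 0.32), and to ENSMUST00000008991, with -3.005 (SE 0.32), both lower in each refed mouse than in each fasted mouse and neither passing the threshold. The 3 refed and 3 fasted ratios did not overlap in 2866 transcripts (18.5%, against 10% by chance), of which 164 were more than 2-fold higher and 477 more than 2-fold lower. Without fasted mouse 1, 144 transcripts were called, 44 higher and 100 lower; leaving out any other animal gave 0. The test with 3 animals per group recovered 0% of simulated log2 changes of 1 in the ratio and 30% of those of 2. In the simulation, log2 changes of 1 in efficiency were thus not detectable, and most of those of 2 were missed.

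The changes in mRNA and in footprints were then set against each other. Across 15483 transcripts tested at both levels, the log2 changes had a Pearson correlation of 0.478, with a slope of 0.38 for footprints on mRNA. Transcripts are not independent replicates. In 3549 transcripts every animal had a whole-number footprint value, the value that undivided reads give, and these held 26.9% to 29.2% of the footprints per library. Across them the correlation was 0.157 and the slope 0.14. The Spearman correlation was 0.086, against 0.342 over all 15483 transcripts. Changes had the same sign at both levels in 50.7% of the whole-number transcripts and 58.8% of all. Of the 395 whole-number transcripts with an unadjusted mRNA p under 0.05, 238 (60.3%) had footprint changes of the same sign. Only 3532 of the 3549 lay outside the footprint-rich and footprint-poor sets described below. The Pearson correlation and slope over those 3532 alone were not computed, so that the part of the sets in them is unknown.

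**Figure D1:**
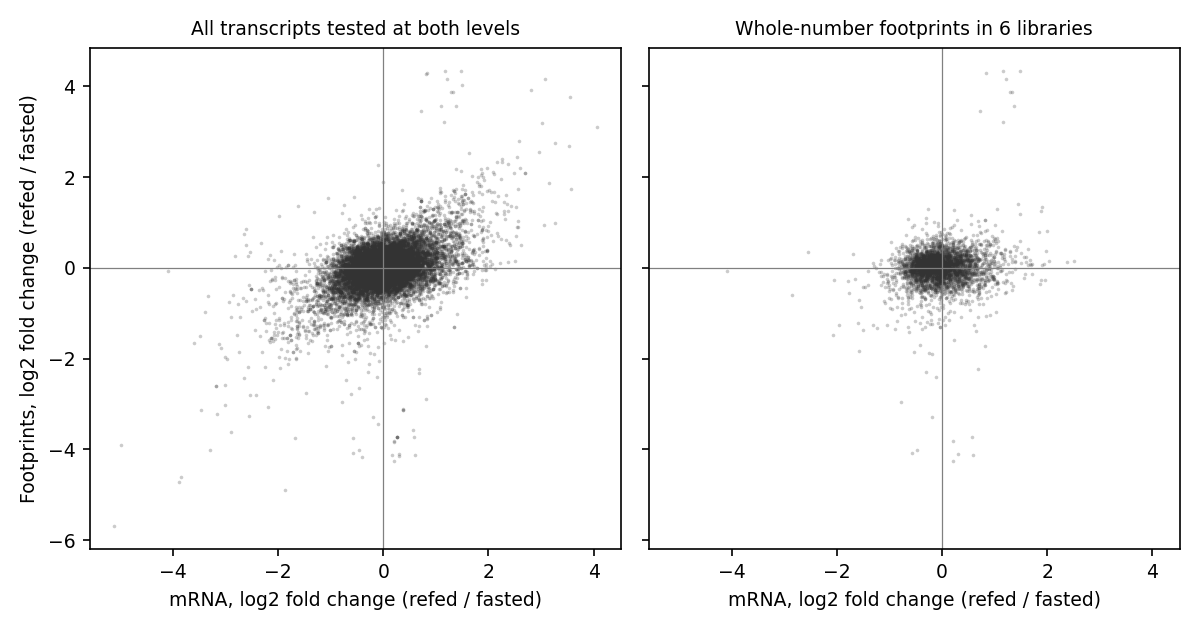
Log2 change on refeeding of mRNA (horizontal axis) and of footprints (vertical axis), 1 point per transcript, for all 15483 transcripts tested at both levels (left) and for the 3549 with whole-number footprints in all 6 animals (right). The cloud rises on the left, less steeply than the diagonal (Pearson r 0.478, slope 0.38), and rises less on the right (r 0.157, slope 0.14).

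Because same-numbered libraries of a feeding group came from 1 mouse, the deviations of each animal from the mean of all animals were compared between its 2 pieces of tissue. Over all transcripts, each of the 6 mRNA libraries correlated best with the footprint library of its own animal, with Pearson values of 0.405 to 0.621. Over the whole-number transcripts the values ranged from -0.202 to 0.253, and 1 of the 6 correlated best with its own animal. Spearman correlations over the same transcripts ran from -0.027 to 0.091, and 0 of the 6 were highest for their own animal. In these transcripts the variance of the ratio within groups had a median of 0.165 (log2 units squared). This lay above the sum of 0.102 for mRNA and 0.0521 for footprints. In transcripts with fractional footprints it was 0.143, below the sum of 0.160 for mRNA and 0.0853 for footprints. Dividing by the mRNA of the same animal did not bring the spread below that of footprints alone in either class.

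**Figure D2:**
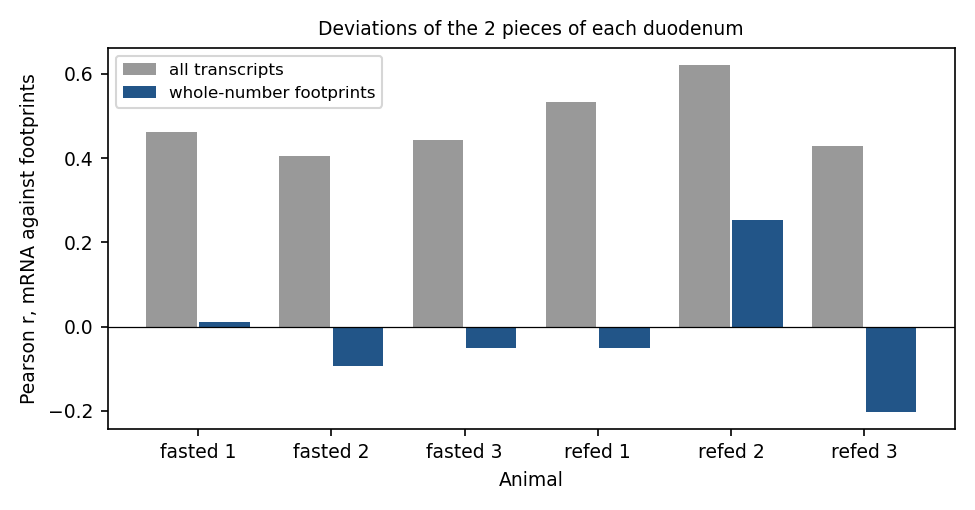
Pearson correlation (vertical axis, no unit) between the mRNA and the footprint deviations of each of the 6 animals from the mean of all animals, over all transcripts (grey bars) and over whole-number transcripts (blue bars). Grey bars lie between 0.405 and 0.621, and blue bars between -0.202 and 0.253.

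To describe the level of translation efficiency, the 2000 most abundant mRNAs were ranked by their mean log2 ratio over the 6 animals. The 90th and 10th percentiles were 0.76 and -2.29, an 8.27-fold range. Footprint reads were not divided by transcript length here, so that the level of the ratio can also depend on length. The ranking and the sets below carry this limit. The group means of fasted and refed mice had a correlation of 0.921 across these transcripts, and the median SD between animals was 0.41 in fasted and 0.29 in refed mice. The lowest mean ratio was that of ENSMUST00000082408, at -10.40 ± 3.03 (SD, n = 6), and the highest that of ENSMUST00000034435, at 9.75 ± 6.09 (SD, n = 6). The latter ranged from 15.04 in fasted mouse 3 to -0.45 in refed mouse 3, and its mRNA was abundant in fasted mouse 1 (586.5 TPM) and refed mouse 3 (690.4 TPM) but between 0.829 and 5.90 TPM in the other 4 animals. These ends of the ranking led to a pair of transcript sets, which were chosen after the values were seen. A footprint-rich set of 23 transcripts had at least 1000 footprints per 1000000 and a log2 ratio of at least 4, and a footprint-poor set of 14 transcripts had at least 1000 TPM of mRNA and a log2 ratio of at most -4, both on means over the 6 animals.

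The footprint-rich set held 40.7%, 41.5% and 44.3% of all footprints in fasted mice 1, 2 and 3, and 31.2%, 4.13% and 0.697% in refed mice 1, 2 and 3. Members not listed in an animal counted as 0, and refed mouse 1 listed 18 of the 23. Over the 18 members listed in all animals, the shares were 35.7%, 35.6% and 39.3% in fasted mice 1, 2 and 3, and 31.2%, 3.56% and 0.606% in refed mice 1, 2 and 3. The exact Clopper-Pearson 95% intervals covered 40.6% to 40.8% for fasted mouse 1, 31.2% to 31.3% for refed mouse 1 and 0.692% to 0.702% for refed mouse 3; they express counting error only. The means were 42.2% ± 1.88 (SD, n = 3) and 12.02% ± 16.7 (SD, n = 3), with an exact two-sided permutation p of 0.1, the smallest that 3 animals against 3 allow (0.2 after Benjamini-Hochberg adjustment over 4 set comparisons). The mRNA of the same set made up 0.926% in fasted mouse 1 and 0.560% in refed mouse 3, and at most 0.0117% in the other 4 animals (exact permutation p = 0.9, n = 3 per group). Of the 18 members listed in all animals and therefore tested, 12 had fewer footprints per 1000000 in every refed than in every fasted mouse, and limma called 0 at either level. The other 5 were not tested.

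The footprint-poor set held 9.97%, 11.8% and 10.2% of the mRNA in fasted mice 1, 2 and 3, and 23.4%, 30.3% and 16.1% in refed mice 1, 2 and 3. The means were 10.6% ± 0.978 (SD, n = 3) and 23.3% ± 7.09 (SD, n = 3), a ratio of 2.19 (exact two-sided permutation p = 0.1, the smallest possible; 0.2 adjusted). The mRNA of 12 of the 14 members was higher in every refed than in every fasted mouse, and that of 1 member was lower in every refed mouse. By limma 0 members passed, and 10 of the higher members and the lower one had an unadjusted p under 0.05. Footprints of this set made up 0.00681%, 0.0156% and 0.00404% in fasted mice 1, 2 and 3, and 0.0129%, 0.291% and 0.829% in refed mice 1, 2 and 3 (exact permutation p = 0.2; 0.267 adjusted, n = 3 per group).

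**Figure D3:**
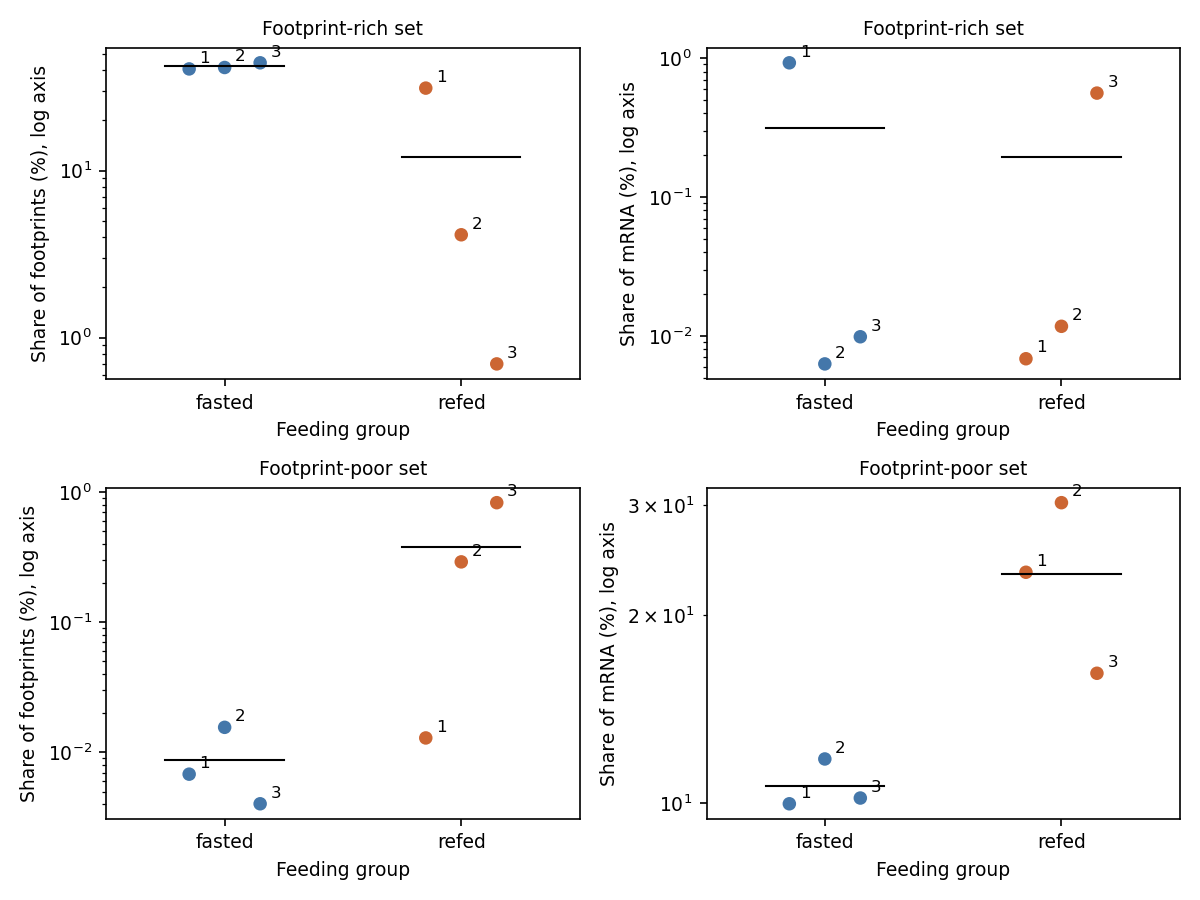
Share of footprints (left) and of mRNA (right), in percent on log axes, of the footprint-rich (top) and footprint-poor (bottom) transcript sets, with fasted mice in blue, refed mice in orange, replicate numbers beside the points and group means as lines. The mRNA share of the footprint-poor set lies between 9.97% and 11.8% in fasted mice and between 16.1% and 30.3% in refed mice, and the footprint-rich set spans 0.697% to 31.2% of the footprints in refed mice.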

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

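All tests in this part were chosen after the results were seen. Transcripts absent from 1 or more files stayed outside the comparisons, and among them 16 were listed in all 3 refed files, with at least 1 TPM and 10 footprint reads in each, and in no fasted file. That lies above the fasted animals, where 7 were listed in that way in fasted files alone. The threshold of 10 reads is easier to reach in the refed libraries, which held a mean of 9.79 M footprint reads against 4.38 M. The part of depth in this difference was not tested. The 18 other sets of 3 animals gave 0 to 15.

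The footprint-rich set fell from 42.2% of the footprints in fasted mice to a mean of 12.02% in refed mice. Lower mRNA as the route of a feeding effect could not be decided, because mRNA and footprints came from different pieces of each duodenum. In refed mice 2 and 3, the 2 members with at least 10 TPM in every animal had few footprints for the mRNA of the other piece. Their footprints per mRNA, relative to the fasted mean, were 0.157 in refed mouse 2 and 0.0271 in refed mouse 3, outside the fasted range of 0.4875 to 1.49. In refed mouse 1 the value was 0.930, inside that range. For the other 21 members the same measure was 0.0539 in refed mouse 2, inside the fasted range of 0.00408 to 1.59. Only refed mouse 3 lay outside. The low end of that range came from fasted mouse 1 alone, where these members held 9142 TPM. They held 23.9 and 28.8 TPM in fasted mice 2 and 3, and 22.9, 70.2 and 5503 TPM in refed mice 1, 2 and 3. Against fasted mice 2 and 3, their mRNA was thus not lower in refed mice 2 and 3, where footprints fell most. For these 21 members the route also stays open through fasted mouse 1. The mRNA of the 18 tested members changed by a median log2 value of 0.254 (-0.578 to 0.597), against -3.77 for footprints. The members rose and fell together between animals, however, and the 95% interval of the difference in the median member between animals ran from -8.08 to 8.71 for mRNA (t interval, n = 3 per group). For footprints the same interval ran from -8.97 to 1.19, so that neither change was firm between animals. A candidate explanation is 1 source of RNA, present in unequal amounts in the pieces of tissue, and it stays open as well. Over 15 distinct members listed in all files, the largest SD of the log2 footprint difference between a fasted and a refed library was 0.694, against at most 0.441 between 2 fasted and 0.617 between 2 refed libraries. The ratio of fasted mouse 3 over refed mouse 3 ran from 20.7 to 103.7 across the members. Over refed mouse 2 it ran from 4.76 to 16.8, and over refed mouse 1 from 0.482 to 2.05. This test replaced a first one, the lowest correlation between any 2 libraries (0.877 over the same members), which does not show whether proportions were kept. Feeding stays open, since the exact p of 0.1 is the smallest that 3 against 3 can give; no source was tested, because the files do not pair transcripts with genes.

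The mRNA of the footprint-poor set rose from a mean share of 10.6% to 23.3%. The 4 most abundant members held 61.9% to 66.4% of the mRNA of the set. A rise carried by them alone is argued against by the other 10 members, whose mRNA was 3.49% to 3.96% in fasted and 5.95% to 11.2% in refed mice, a ratio of means of 2.31; this test replaced a count of members that could not decide it. Footprints did not follow the mRNA in every animal: footprints per mRNA, relative to the fasted mean, were 64.0 in refed mouse 3 and 11.97 in refed mouse 2, but 0.687 in refed mouse 1, inside the fasted range of 0.494 to 1.65. Refed mice 2 and 3 are the animals with the lowest footprint-rich shares, and a difference in how these libraries were prepared could not be tested because the labels give no batch. Feeding and time of day cannot be told apart as the source of the mRNA difference (exact p = 0.1, the smallest possible).

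The pieces of 1 duodenum deviated together across transcripts with fractional footprints (mean Spearman correlation 0.414) and not across whole-number transcripts (0.0109). This is consistent with reads having been divided in proportion to mRNA abundance, which copies mRNA deviations into footprints. Labels exchanged within a feeding group cannot be told apart from pieces that share no deviations: in the best of 36 assignments the lowest of 6 correlations was -0.00778. Among 95 whole-number transcripts with an mRNA p under 0.01, the stated feeding split of the footprint libraries gave a correlation of 0.587 with mRNA changes. The highest other split gave 0.559 in absolute value. The 95% bootstrap interval of the difference ran from -0.102 to 0.174. It resampled transcripts and not animals, so it does not measure the spread between animals. An exchange of feeding labels between library types stays open. Different contents of the pieces may also contribute and were not tested.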

How the results depend on the processing

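Counts of called transcripts changed with the processing, and the cause was not tested unless stated. For mRNA (1 call), no filter gave 2 and a pseudocount of 0.1 gave 3. All 12 libraries in 1 fit, without a term for the animal, gave 176. Leaving out 1 animal gave 0 to 54. For footprints (5 calls), the strict filter gave 3, a pseudocount of 0.1 gave 2 (0 of the 5), the replicate block by number gave 0 and 1 fit of all libraries gave 20; leaving out 1 animal gave 0 to 32. For translation efficiency (0 calls), leaving out 1 animal gave 0 to 144, and the other fixed alternatives gave 0, including the fit with no replicate block (1290 at an unadjusted p under 0.05, against 1941, which leaving out 1 animal moved to 1084 to 3215).

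Alternatives chosen after the data were examined gave the following. With absent transcripts set to 0, calls were 19 for mRNA, 37 for footprints and 1 for translation efficiency. Whole-number transcripts alone, a smaller number tested (3549), gave 4, 2 and 0. Without scaling, footprints gave 23 calls, with the 5 of the report among them, and the median log2 change became 0.52; for translation efficiency it became 0.56 with 0 calls. Removing both transcript sets gave 8 footprint calls, 5 of them shared with the main result, and voom weights gave 0. Transcripts passing both filters alone gave 1 mRNA and 5 footprint calls.

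The replicate block by number gave 1 call for mRNA, another transcript than in the report (ENSMUST00000129753 had a limma adjusted p of 0.136), and 0 for translation efficiency. Fasted and refed mice shared only a number: same-number correlations of deviations were -0.00318, 0.125 and -0.118 for mRNA and 0.174, 0.169 and 0.0455 for footprints. Every library correlated best with its own number for footprints but not for mRNA. The named transcripts kept their direction in all 192 recomputed values, with 26 losing and 10 gaining significance. DESeq2, gene lists, the ribosomal protein comparison, removal of a transcript list and another count column were not run. Depth limited low transcripts most in fasted mouse 1 (2.39 M footprint reads (M, 1000000)).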

Other observations

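All tests in this part were chosen after the results were seen. Of the 15483 transcripts tested for translation efficiency, the 3871 with the most abundant mRNA had a median log2 ratio, relative to all transcripts of the animal, of -0.19 ± 0.13 (SD, n = 3) in fasted and -0.04 ± 0.06 (SD, n = 3) in refed mice. The 3871 with the least abundant mRNA had 0.34 ± 0.09 and 0.23 ± 0.04 (SD, n = 3). The same mRNA values ranked the transcripts and formed the denominator of the ratio. Error in mRNA alone therefore gives lower ratios at high abundance, and the difference between ranges is no result about translation. The exact permutation p was 0.1 for the first and 0.2 for the second (0.2 and 0.267 adjusted over 4 ranges of abundance), where 0.1 is the smallest possible.

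The 6 animals were regrouped into all 10 splits of 3 and 3, too few for a share under 0.05. For mRNA the real split called 1 transcript and the highest other 3, and 4 of the splits gave as many as the real one; at an unadjusted p under 0.05 the real split counted 2397 and the highest other 1985 (1 split as large, the real one). For footprints the real split called 5 and the highest other 3, with 1693 and 1301 at an unadjusted p under 0.05 (in both, 1 split as large, the real one); the 1693 fell to 918 without refed mouse 3 and to 1088 without refed mouse 2. For translation efficiency all 10 splits called 0, and at an unadjusted p under 0.05 the real split counted 1941 and the highest other 2193 (2 splits as large). That other split set fasted mouse 1 and refed mice 1 and 3 against the rest, and the same split gave the highest other unadjusted count for mRNA and for footprints.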
